A study of Mus musculus with 18 samples.

How the data were processed

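Total RNA of fore footpad skin was measured on a two-colour Agilent array (NIA Mouse 44K v3.0). Per the labels, RNA was extracted with Trizol, precipitated with LiCl and amplified with a low-input kit, and the skin RNA was labelled with Cy3 and the common reference with Cy5 on every array, without a dye swap. The design text calls the 3 animals per group embryos although the ages are postnatal, and they are treated here as 3 separate animals. The 18 arrays were spread over 5 slides, identified from the scanner files.

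For each array the deposited scanner file holds spot brightness and local background as intensity in both channels, made per the file headers with Agilent Feature Extraction 9.5.1.1. The same deposited files hold processed signals, with background subtracted and dyes normalized by that software, as intensity, and a ratio of reference over skin in log10 units. They also hold other values, namely marks of 0 or 1 per spot for saturation, outliers and signal well above background, as deposited by the authors. The authors also deposited a value table of 25030 probes in log10 units, with column medians between 2.42 and 2.48. Over the 13577 of its probes that were well above background on all 18 arrays, its values minus their probe mean were checked against the log10 ratio of skin over reference from the processed signals, and had a slope of 1 on it and a largest difference of 2.0e-04, so the table holds that ratio plus a constant per probe.

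From the scanner files, mean spot brightness and median local background were corrected with normexp at an offset of 50 and normalized within each array by loess, with control and outlier spots given no weight, in limma 3.58.1 under R 4.3.3. The sign was turned to skin over reference on the log2 scale, outlier spots were set to missing (1 to 13 per array), and the 42034 spots were averaged to 42006 probes. Probes well above background in Cy3 on at least 3 arrays were kept (27118), and 2 of these were left out for missing values, leaving 27116. Linear models with 6 group means were fitted over all 18 arrays with lmFit and eBayes (12 residual degrees of freedom). Contrasts were knockout against wild type at P10, P14 and P31, their mean, wild-type P14 against P10 and P31 against P14, and an F test of the interaction. A probe passed with a Benjamini-Hochberg adjusted p under 0.05 over all tested probes and a fold over 1.5, limits that the series design names; the interaction had no fold limit. P values of limma are two-sided, and its adjusted p values are the ones printed. No test of the 3 against 3 arrays of one age by permutation can go below a share of 0.1.

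Where a group was not well above background on any of its arrays, no fold was taken from the fit, and a bound was computed from the Cy3 channel after loess and Aquantile normalization. The brighter group's mean was set against a floor averaged over the arrays of the dimmer group, namely the lowest Cy3 level called well above background on the array, or the probe's own level where that was higher. A constant dye bias of a probe is common to both groups of such a bound, and one that varies with brightness or between arrays stays open, since dyes were never swapped. Principal components were computed from the log2 ratios of the tested probes, centred per probe.

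The comparisons, the limits, the filter and the alternatives were fixed before the data were examined, as was a rule for naming genes. That rule took genes that passed and whose 3 arrays of one group lay on one side of those of the other group (for the mean, the same sign at every age), ordered by size. It could not be applied to genes, because 0 probes carry a gene name in the scanner files, a platform annotation was not used here, and the reference at hand holds no sequence to place the probes. The rule was applied to probes instead, and at most 2 that rose and 2 that fell were named in each comparison. For the same reason the level of Foxa1, the tests of gene lists, the markers of other cell types and the genes named in the series title were not analysed here. Whether other tissue was present in a skin sample was therefore not checked.

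Alternatives were no background correction, an offset of 0, the log ratio of the scanner software, Aquantile normalization between arrays, Cy3 alone scaled to the 75th percentile, the deposited value table, no filter, a filter on all 18 arrays, a mean log10 Cy3 signal over 2.0, no fold limit, an ordinary linear model per probe without variance moderation, as in the ANOVA that the design names,, a fit of the 6 arrays compared, slide as a fixed block or a random effect, the replicate number as a block, and leaving out each array in turn. The log base of the intensity limit in the series design is not given, and log10 was assumed. Slide as a fixed block equals the contrast within the slide that holds both genotypes at an age, with 1 knockout and 3 wild-type arrays at P10 and P31 and 3 and 1 at P14. Whether replicate numbers pair a knockout with a wild-type animal is not stated. After removal of group means, the arrays of one number correlated across probes at P10 (r = 0.214, 0.354 and 0.171), so the numbers were read as pairs at that age, from the data and not from the labels. At P14 and P31 some arrays of one number had a negative r, so a match by chance at P10 is not excluded. Array quality weights, the knockout contrasts with age and their agreement with the wild type were added after the data were seen.

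The calling steps were tested on simulated data, in which 200 of 27116 probes were changed by 1.75-fold to 4-fold. At P10 72.0% of the changed probes were recovered at 1.75-fold and 86.0% at 2-fold, with 7 false calls. In the mean over the ages 92.0% and 98.0% were recovered, with 2 false calls. The simulated noise was independent between probes and arrays, without the spread along a shared axis described below. More probes were changed than passed in the knockout comparisons. Recovery may thus be lower, and false calls more frequent, in the real data. Files were read with the data.table package (version 1.17.8), and figures were drawn with matplotlib 3.10.9 under Python 3.11.15.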

Results

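Gene expression was measured in hairless skin of the fore footpad, the site of the mouse sweat glands, from FoxA1 knockout mice and wild-type littermates of the C57BL/6 strain. FoxA1 is a forkhead transcription factor. Skin was taken at postnatal days 10, 14 and 31 (P10, P14 and P31), with 3 arrays for each genotype and age, which gave 6 groups and 18 arrays. The labels give the sex as mixed and do not give it per animal. On every array the skin RNA carried Cy3 and was hybridized against the same Cy5-labelled reference, a pool of RNA from 11 mouse cell lines with added embryonic stem cell RNA. Each array held 42006 probes of 60 bases for transcripts. Between 53.3% and 63.7% of the probes were well above background in the skin channel, and the median spot brightness of that channel was 107 to 188 against a local background of 44 to 54. No spot was saturated in the skin channel. The scanner files and the value table give no gene name or position for any probe and a platform annotation was not used here, so probes are named by their identifier and sequence. The number of arrays limits the precision of every value, and errors after ± are the SD of 3 arrays.

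The first principal component of the 27116 probes tested held 43.0% of the variance and ordered the arrays by age, from scores of 27.0 to 52.2 at P10 to scores between -53.2 and -21.5 at P31. The second component held 21.2% and parted arrays of the same genotype and age. At P14 it also parted the genotypes, with scores of -49.7 to -21.6 in the wild type and -14.5 to -0.491 in the knockout. At P31 knockout replicate 3 and wild-type replicate 2 had scores of 45.5 and 48.9 on it, whereas the other four arrays of that age lay between -5.96 and 9.09. The correlation of log2 ratios across probes had a median of 0.979 between arrays of one group and 0.953 between arrays of different groups, and the ranges overlapped (0.952 to 0.991 and 0.892 to 0.988).

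**Figure D1:**
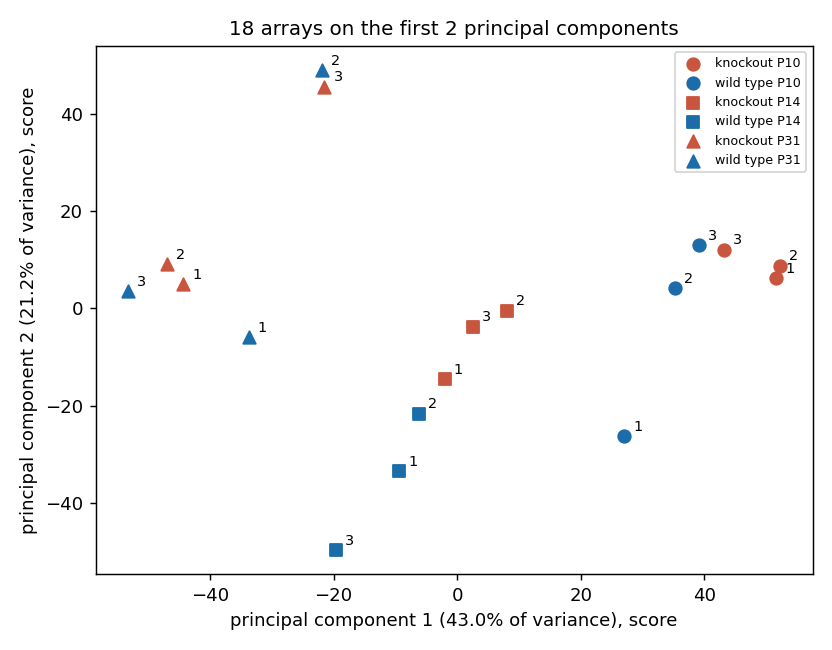
Scores of the 18 arrays on principal components 1 (43.0% of the variance) and 2 (21.2%) of the log2 ratios of skin over reference, with color for genotype, marker shape for age and the replicate number beside each point. Ages separate along the first component, and knockout replicate 3 and wild-type replicate 2 of P31 stand apart on the second at 45.5 and 48.9.

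The comparison of genotypes at P10 asked which transcripts differed in footpad skin without FoxA1 at the youngest age. Few transcripts differed, and most of these were lower in the knockout. Probe Z00047679-1 (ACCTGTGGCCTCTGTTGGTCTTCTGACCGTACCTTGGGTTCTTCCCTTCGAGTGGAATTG) fell from a log2 ratio over the reference of 3.60 ± 0.05 in the wild type to 0.05 ± 0.16 in the knockout, a change of -3.55 (SE 0.267, adjusted p = 4.8e-06) or 11.7-fold, and of -4.82 with the Cy3 channel alone. Probe Z00025973-1 (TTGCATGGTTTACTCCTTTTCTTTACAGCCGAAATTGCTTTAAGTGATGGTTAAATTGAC) had a log2 ratio of 0.32 ± 0.14 in the wild type and was not well above background on any knockout array, so that it was at least 7.05-fold lower (adjusted p = 5.6e-06). Of the probes that rose, Z00026567-1 (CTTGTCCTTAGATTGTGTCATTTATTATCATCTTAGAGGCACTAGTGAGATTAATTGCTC) went from 0.73 ± 0.31 to 2.36 ± 0.51, a change of 1.63 (SE 0.247, adjusted p = 0.0191). The other, Z00028477-1 (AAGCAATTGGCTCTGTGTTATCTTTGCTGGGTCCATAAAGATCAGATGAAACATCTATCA), was not well above background in the wild type and was at least 1.25-fold higher in the knockout (adjusted p = 0.0175). By limma 8 of 27116 probes passed at P10, 2 higher and 6 lower, while 906 (3.34%) had an unadjusted p under 0.05. The split was 1 higher and 7 lower without background correction, 1 and 8 with an offset of 0, and 1 and 6 with the log ratio of the scanner software. On the slide that held both genotypes at P10, the change of Z00047679-1 was -3.48 (adjusted p = 1.6e-04), and Z00025973-1 was lower in the knockout too (adjusted p = 0.00622). Neither rise passed on that slide (1.06 for Z00026567-1, adjusted p = 0.998 for each), and neither passed with the replicate number as a block, which left the sizes as they were (adjusted p = 0.280 and 0.349). Over all alternatives the adjusted p of Z00026567-1 ran from 2.2e-04 to 1.00, with the call lost in 8 of 13, among them an offset of 0, the log ratio of the scanner software, Cy3 alone and the deposited values, and it was lost without knockout replicate 1 or 2 or wild-type replicate 1 or 3 of P10; that of Z00028477-1 was lost in 3 of 13 and without any one of the 6 arrays of P10. The count became 4 with slide as a block, 4 when every array had to be well above background, 13 without knockout replicate 3 (6 higher and 7 lower), and 185 with array quality weights (81 higher and 104 lower), so the excess of lower probes is small in these last fits.

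At P14 the comparison asked the same question at the second age. The transcripts of the same 2 probes were again lower in the knockout. Z00025973-1 stood at 0.65 ± 0.38 in the wild type and was not well above background on any knockout array, at least 8.21-fold lower (adjusted p = 2.9e-05). Z00047679-1 went from 4.28 ± 0.23 to 1.13 ± 0.35, a change of -3.14 (SE 0.267, adjusted p = 2.9e-05) or 8.84-fold, and of -5.55 with the Cy3 channel alone. The single probe that rose, Z00023161-1 (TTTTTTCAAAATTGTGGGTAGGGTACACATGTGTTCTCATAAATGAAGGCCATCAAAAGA), went from -1.01 ± 0.28 to 0.20 ± 0.26 (SE of the change 0.191, adjusted p = 0.0356). By limma 7 probes passed, 1 higher and 6 lower, and 2553 (9.42%) had an unadjusted p under 0.05. With the log ratio of the scanner software 4 were higher and 8 lower, and with the deposited values 4 were higher and 6 lower. On the slide with both genotypes the changes were -3.23 for Z00047679-1 (adjusted p = 4.0e-04) and 1.33 for Z00023161-1 (adjusted p = 0.241), and Z00025973-1 was lower in the knockout (adjusted p = 0.0260). The call of Z00023161-1 was also lost, with the size of 1.20 kept, without variance moderation (adjusted p = 0.150), with the 6 arrays of P14 alone (adjusted p = 0.0659), and without any one of 10 arrays (changes of 1.11 to 1.20, adjusted p up to 0.341). The count was 14 with the 6 arrays of P14 alone and 43 with array quality weights (20 higher and 23 lower).

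At P31 the comparison asked what differed at the oldest age. All probes that passed were lower in the knockout. Z00025973-1 had a log2 ratio of 0.58 ± 0.72 in the wild type, was not well above background on any knockout array, and was at least 7.99-fold lower (adjusted p = 5.4e-05). Z00027353-1 (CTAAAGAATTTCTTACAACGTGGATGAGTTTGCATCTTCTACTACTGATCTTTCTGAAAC) was at 2.73 ± 0.79 in the wild type and not well above background in the knockout, at least 6.04-fold lower (adjusted p = 2.0e-04). By limma 4 probes passed, 0 higher and 4 lower, and 2116 (7.80%) had an unadjusted p under 0.05; the log ratio of the scanner software gave 1 higher and 3 lower. On the slide with both genotypes Z00025973-1 and Z00027353-1 were lower in the knockout (adjusted p = 0.00164 and 0.0435), while with the 6 arrays of P31 alone neither passed (adjusted p = 0.160 and 0.489) and the count was 0, with 635 at an unadjusted p under 0.05. Array choice moved the count most: it was 269 (74 higher and 195 lower) without wild-type replicate 3, 13 without knockout replicate 2, 9 with slide as a block (4 higher and 5 lower), 8 with slide as a random effect, 2 without variance moderation or with array quality weights, and 1 when every array had to be well above background.

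The mean of the 3 genotype differences asked which effects of the knockout were shared by the ages. Transcripts lower without FoxA1 again outnumbered those that were higher. Z00047679-1 fell by 2.95 on the log2 scale over the ages (SE 0.154, adjusted p = 1.7e-08) or 7.74-fold, with a change of -5.09 from the Cy3 channel alone, and Z00025973-1 was below its wild-type level by the bounds given for each age (adjusted p = 7.9e-09). Both passed at each of the 3 ages in the fit of all arrays, and Z00025973-1 was well above background on all 9 wild-type arrays and on 0 of 9 knockout arrays. At P31 neither passed with the arrays of that age alone. Z00047679-1 also lost its call at P31 without variance moderation and with the replicate number as a block. In the knockout Z00047679-1 went from 0.05 ± 0.16 at P10 to 1.13 ± 0.35 at P14 and 2.06 ± 0.74 at P31, a rise of 2.01 between P10 and P31 (adjusted p = 3.2e-05). Its difference between the genotypes at P31 was -2.17 (adjusted p = 0.00353), or -2.99 on the slide with both genotypes. The test that the difference varied with age did not pass (adjusted p = 0.792). Z00023161-1 was higher by 1.00 (SE 0.110, adjusted p = 2.7e-04), with changes of 0.63, 1.20 and 1.16 at P10, P14 and P31. Z00076265-1 (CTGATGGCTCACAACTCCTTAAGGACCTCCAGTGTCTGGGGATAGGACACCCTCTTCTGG) was higher by 1.94 (SE 0.274, adjusted p = 0.00457), with -3.01 ± 0.08, -2.24 ± 1.03 and -2.41 ± 1.04 in the wild type and -0.27 ± 0.46, -0.66 ± 0.44 and -0.91 ± 0.39 in the knockout at the 3 ages in turn; wild-type replicate 2 of P14 (-1.07) and wild-type replicate 3 of P31 (-1.21) lay within the range of the knockout arrays.

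By limma 18 probes passed in the mean over the ages, 2 higher and 16 lower, and 17 of them had the same sign at every age. An unadjusted p under 0.05 was found for 3213 probes (11.85%). The 16 include Z00026330-1 (adjusted p = 1.6e-04), which passed at P10 alone, and Z00027353-1 (adjusted p = 0.0120), which passed at P31 alone. A call in the mean is thus not a sign of an effect shared by the ages. All 3 knockout arrays lay below all 3 wild-type arrays at every age for 11 probes and above them for 1; these probes were called on the same arrays, so the share of 0.1 that chance gives at a single age for unselected probes is no reference for them. The log ratio of the scanner software gave 9 higher and 17 lower, and the deposited value table gave 7 higher and 17 lower. The calls of the single ages overlapped: P10 and P14 shared 5 probes, where independent draws from the tested probes give 0.00207 (one-sided exact hypergeometric p = 9.6e-18), and P31 shared 2 with each of them (p = 4.6e-07 and 3.4e-07), those being Z00025973-1 and Z00047679-1. These tests treat probes as independent, although several probes can report one transcript. They also treat the ages as independent, although the shared fit gave a probe the same variance at every age. Z00076265-1 no longer passed with slide as a block (1.88, adjusted p = 0.126), with the replicate number as a block (adjusted p = 0.0534) or without variance moderation (adjusted p = 0.0635), and the changes on the slides with both genotypes were 2.21, 2.06 and 1.37. The count was 30 with the Cy3 channel alone, 11 without variance moderation or with the replicate number as a block, and 10 when every array had to be well above background.

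**Figure D2:**
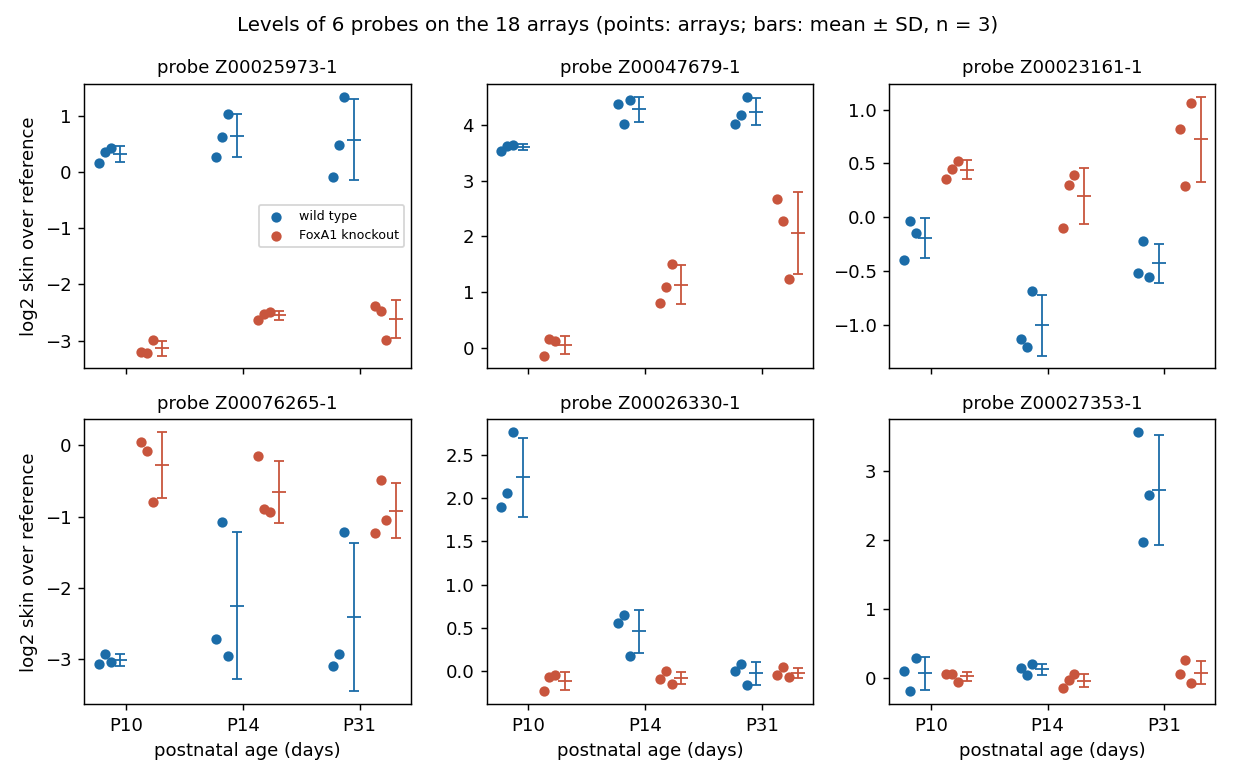
Log2 ratio of skin over reference of 6 probes against postnatal age, with one point per array, wild type in blue and FoxA1 knockout in red, and bars for the mean ± SD (n = 3). Z00025973-1 and Z00047679-1 are lower in the knockout at each age, Z00026330-1 differs at P10 (2.24 ± 0.46 in the wild type) and Z00027353-1 at P31 (2.73 ± 0.79).

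The interaction of genotype and age asked whether the effect of the knockout changed between ages. Transcripts of 2 probes, each brightest in the wild type at one age, met this test. Z00026330-1 (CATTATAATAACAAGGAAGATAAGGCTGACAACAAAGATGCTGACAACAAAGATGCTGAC) was at 2.24 ± 0.46 in the wild type at P10, 0.46 ± 0.25 at P14 and -0.03 ± 0.13 at P31, and was not well above background on any knockout array. It was at least 3.60-fold lower in the knockout at P10 (adjusted p = 4.8e-06). At P14, where 1 wild-type array was well above background, it did not pass (adjusted p = 0.524). At P31 it was not above background in either genotype. Z00027353-1, the probe at least 6.04-fold lower at P31, was not well above background in either genotype at P10 or P14. By the limma F test 2 probes passed, Z00026330-1 (adjusted p = 0.00299) and Z00027353-1 (adjusted p = 0.0256), and 1448 (5.34%) had an unadjusted p under 0.05. Both calls were lost with an offset of 0, without variance moderation and with slide as a block (adjusted p up to 1), Z00026330-1 also with Cy3 alone (adjusted p = 0.483), and Z00027353-1 also without any one of 13 arrays (adjusted p up to 0.116). The count ranged from 0 to 4 over the alternative settings and was 155 without wild-type replicate 3 of P31.

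Wild-type skin at P14 and P10 was compared to describe normal footpad between these ages. Many transcripts changed, and more fell than rose. Z00039540-1 (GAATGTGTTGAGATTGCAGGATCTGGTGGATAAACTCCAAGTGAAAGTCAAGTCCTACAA) went from 2.38 ± 0.45 to 0.07 ± 0.38, a change of -2.31 (SE 0.246, adjusted p = 2.2e-04), or -2.97 with the Cy3 channel alone. Z00034035-1 (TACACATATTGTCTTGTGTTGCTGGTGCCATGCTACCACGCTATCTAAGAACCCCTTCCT) went from 0.50 ± 0.40 to -1.75 ± 0.18, a change of -2.25 (SE 0.313, adjusted p = 0.0011). Z00026161-1 (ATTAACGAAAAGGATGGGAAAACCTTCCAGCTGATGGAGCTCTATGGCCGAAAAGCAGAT) rose from 2.33 ± 0.34 to 5.16 ± 0.53, a change of 2.83 (SE 0.598, adjusted p = 0.0106), and Z00031175-1 (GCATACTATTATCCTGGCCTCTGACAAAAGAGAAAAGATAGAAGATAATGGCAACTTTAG) rose by 2.51 (SE 0.645, adjusted p = 0.0243). By limma 1828 probes passed, 667 higher and 1161 lower, with a median size of 0.76 on the log2 scale. No slide held P10 together with a later age, so slide and age cannot be told apart here; Z00031175-1 was lost without variance moderation (adjusted p = 0.0561) and without any one of 5 arrays (adjusted p up to 0.0979). The count was 3337 without a fold limit, 1206 without variance moderation, 3042 with array quality weights, and 492, 680 and 513 without wild-type replicate 2 of P10, replicate 3 of P10 and replicate 3 of P14.

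The same question was asked of the wild type between P14 and P31. Many transcripts changed here too, and which direction held more of them depended on the arrays and on the slide term. Z00023589-1 (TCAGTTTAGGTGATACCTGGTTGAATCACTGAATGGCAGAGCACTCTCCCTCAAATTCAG) rose from 0.71 ± 0.07 to 5.14 ± 0.23, a change of 4.44 (SE 0.229, adjusted p = 3.1e-08) or 21.6-fold, and of 5.41 with the Cy3 channel alone. Z00027353-1 was not well above background at P14 and was at least 5.10-fold higher at P31 (adjusted p = 1.1e-05). Z00034035-1 fell further, from -1.75 ± 0.18 to -5.06 ± 0.49, a change of -3.32 (SE 0.313, adjusted p = 8.7e-06) or -2.68 with slide as a block, and Z00025051-1 (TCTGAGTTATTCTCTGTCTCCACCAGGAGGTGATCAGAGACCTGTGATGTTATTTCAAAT) went from 3.17 ± 0.51 to -0.03 ± 0.42, a change of -3.20 (SE 0.236, adjusted p = 1.0e-06) or -4.27 with the Cy3 channel alone. By limma 1897 probes passed, 713 higher and 1184 lower (1351 and 1342 without wild-type replicate 1 of P31), with a median size of 0.82 on the log2 scale. The slides of these groups are linked through knockout arrays alone, and with slide as a block 236 probes passed (128 higher and 108 lower), of which 153 were among the 1897; more were then higher than lower. The count was 3101 without a fold limit, 768 with the 6 arrays of these groups alone, and 1232 without wild-type replicate 2 of P31.

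The changes with age in the wild type were then looked up in the knockout arrays, which are other animals. This comparison was added after the data were seen. In each genotype the arrays of the compared ages lay on different slides, and the genotypes shared some of these. An effect of slide can therefore also give equal signs in both genotypes. Probes that changed in the wild type mostly had the same sign of change in the knockout, where fewer passed the test. Of the 667 probes higher at P14 than at P10 in the wild type, 655 (98.2%) had a positive change in the knockout, with a median log2 change of 0.58 against 0.73 in the wild type, and 266 passed there as well. The probes were chosen by passing in the wild type, which favours larger values there. A smaller median and fewer calls in the knockout can follow from that choice alone. Of the 1161 lower probes 1154 (99.4%) had a negative change in the knockout, and 476 passed. Between P14 and P31, 604 of 713 higher probes (84.7%) and 1162 of 1184 lower probes (98.1%) had the same sign in the knockout, and 228 and 671 passed. Z00023589-1 rose by 5.49 in the knockout, and Z00034035-1 changed by -3.26 and -2.51 in the successive intervals. Z00027353-1 was not well above background on any knockout array at P14 or P31. Among probes without a call in the wild type, 79.1% and 66.1% had the same sign in both genotypes in these intervals, and Pearson's r across all probes was 0.799 and 0.646; probes are not independent replicates. Without wild-type replicate 3 of P31 the share for higher probes between P14 and P31 was 65.1%, and that for lower probes was 87.6%. The share for higher probes was then no greater than the 66.1% of uncalled probes in the fit of all arrays.

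**Figure D3:**
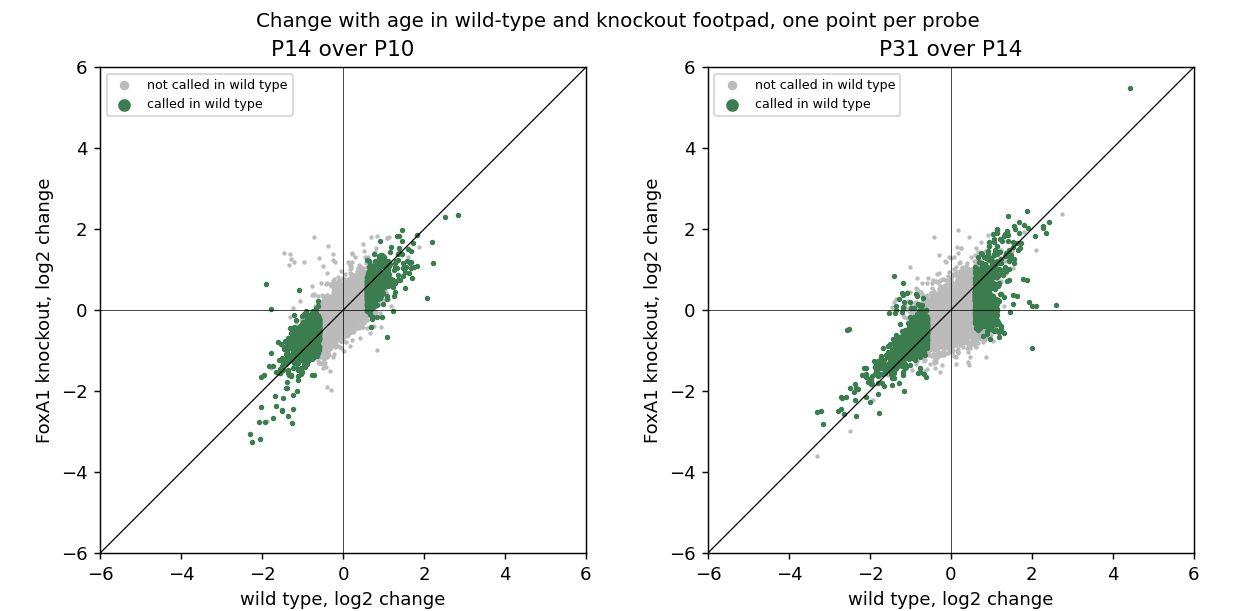
Log2 change with age in the wild type (horizontal axis) against the FoxA1 knockout (vertical axis) for P14 over P10 and P31 over P14, with one point per probe, probes called in the wild type in green and a diagonal line of equality. Called probes lie mostly in the quadrants of equal sign, with 98.2% and 84.7% of those higher and 99.4% and 98.1% of those lower in the wild type having the same sign in the knockout. Within each genotype the compared ages lay on different slides.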

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

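The tests of genotype labels, of the age course at P31 and of a sequence variant were chosen only after the results were seen. The effect of the knockout differed between the ages, by the interaction test itself, for Z00026330-1 (adjusted p = 0.00299) and for Z00027353-1 (adjusted p = 0.0256). Z00026330-1 was well above background on 3 wild-type arrays at P10, 1 at P14 and 0 at P31, and Z00027353-1 on 0, 0 and 3, against 0 knockout arrays of each age for both. When genotypes were regrouped within each age, 8 of 100 regroupings, the real one included, gave at least the real count of 2 probes, and the highest of the others gave 1416, so chance is not excluded for that count. Groups of 3 arrays were not tested for outlying arrays.

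The 6 arrays of P31 part across the genotypes: knockout replicates 1 and 2 with wild-type replicate 3 differed from the remaining arrays in 1075 probes, 782 higher and 293 lower, against 4 between the genotypes; the knockout replicates 1 and 2 share a slide and the other 4 arrays share another, so that wild-type replicate 3 alone breaks a split by slide, and slide stays open. Swapped genotype labels of knockout replicate 3 and wild-type replicate 3 are argued against, since 0 of 10 probes called at P10 or P14 had both arrays nearer to the other genotype (wild-type replicate 3 alone in 3, knockout replicate 3 in 0). The 3 were Z00026330-1, Z00026567-1 and Z00028477-1, which did not pass at P31 by limma (adjusted p = 0.997, 0.841 and 0.994). No array of P31 was well above background for them, except 1 wild-type array for Z00026567-1. Their nearness at P31 therefore does not bear on the labels. The difference between these sets of arrays correlated across probes with the P14 minus P10 difference of both genotypes (r = 0.522, or 0.497 after removing trends with GC content), so that animals at different points of the age course may account for part of it. The slide of knockout replicates 1 and 2 also held 2 wild-type arrays of P14, so an effect of slide can raise this r as well. The correlation of the set difference with the wild-type P31 minus P14 difference was -0.285, a value that shared arrays push down, and 110 of the 1075 probes were called in that comparison. The median GC content was 51.7% in the probes higher in the first set, 41.7% in those lower and 45.0% in all tested probes, and the sex of the animals stays open as untested.

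Arrays of one group spread along one shared axis, which held 33.9% of the variance within groups, with its highest scores at P31 for wild-type replicate 2 (0.518) and knockout replicate 3 (0.455). The Cy5 reference is argued against as its source, since it carried 3.71% of the variance of the probes' slopes on the axis. GC content of the probes is argued against as the whole cause, since the axis still held 32.0% after removal of each array's GC trend, although slopes and GC content were correlated (Spearman's rho = -0.334 across probes). Slide took 32.1% of the variance of the arrays' scores, against a median of 16.6% over 20000 permutations (permutation p = 0.255), and stays open because the arrays are too few to decide. Differences in dissection, sex or stage between animals were not tested.

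For Z00076265-1, replicate 2 of the wild type at P14 (-1.07) and replicate 3 at P31 (-1.21) lay at the level of the knockout arrays (-1.22 to 0.05), and the other 7 wild-type arrays lay between -3.09 and -2.72. For a wrong genotype label on the 2 arrays, 0 of the 17 other probes called in the mean over the ages had both nearer to the knockout mean. Those probes were called with the 2 arrays counted as wild type, which favours this outcome, so this count cannot decide. Z00025973-1, which also passed at P10 from other arrays, was well above background on both arrays and on no knockout array. Its log2 ratios on the 2 arrays were 0.63 and 1.35, against -2.38 at most on a knockout array. Z00047679-1, which also passed at P10, had 4.02 and 4.50, against 2.67 at most. Z00046430-1, Z00051811-1 and Z00054396-1, lower in the knockout at P10 too, lay on both arrays above every knockout array of that age. Z00026330-1 did so at P14 and was not well above background in either genotype at P31. These levels argue against a wrong label on the 2 arrays. The shared axis between arrays is argued against, with r = -0.0934 between its scores and the probe's deviations from the group means over the 18 arrays. A sequence variant near the disrupted gene, inherited together with the knockout allele, may give levels in separate clusters, and the largest gap between neighbouring arrays was 1.50 on the log2 scale. That explanation stays open, because the position of the probe is not given in the files used.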

How the results depend on the processing

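Array quality weights were chosen only after the data were seen; all other alternatives were planned. No named probe changed its direction under any alternative run. The excess of falls over rises between wild-type P14 and P31 turned with slide as a fixed block (128 higher, 108 lower) and without wild-type replicate 1 of P31 (1351 higher, 1342 lower). Apart from leaving out arrays, counts stayed within 1.5-fold of the reported count in 75 cases and moved beyond it in 31. Except where said, the cause was not tested. With a filter on all 18 arrays, which tests fewer probes (20403), the counts were 4 at P10, 1 at P31, 10 in the mean over the ages and 0 for the interaction (1031 at an unadjusted p under 0.05 by limma). That filter leaves out in advance any probe that is dim on even 1 array, among them Z00025973-1 and both probes of the interaction. All calls that remained at P10, at P31 and in the mean were among those reported. The lower counts are thus no evidence against the calls left out. Slide as a fixed block, with fewer arrays behind each contrast, gave 4 at P10, 9 at P31, 236 for wild-type P31 against P14 and 1 for the interaction, none of it shared with the reported 2. A random slide effect gave 8 at P31. Without variance moderation the counts were 2 at P31, 11 in the mean, 1206 for wild-type P14 against P10 and 0 for the interaction (1493 unadjusted). Array quality weights, which were 0.332 to 0.848 at P31, gave 185 at P10, 43 at P14, 2 at P31 and 3042 for wild-type P14 against P10. The 6 arrays alone, with fewer arrays for the spread, gave 14 at P14, 0 at P31 (635 unadjusted) and 768 for wild-type P31 against P14. Without a fold limit, which admits smaller changes, 3337 and 3101 probes passed in the wild-type comparisons. The log ratio of the scanner software gave 12 at P14, and Cy3 alone gave 30 in the mean and 1 for the interaction. For the interaction an offset of 0 gave 0 (1643 unadjusted) and the deposited values 4. The mean signal limit gave 0, since it was applied to the calls of the reported fit and left out both probes.

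With the replicate number as a block the count was 6 at P10, where the calls of both rises were lost at unchanged sizes and no other call of a named probe changed. At P14 (r of same-numbered arrays -0.428, 0.383 and -0.308) and P31 (0.373, -0.300 and -0.457) the arrays share only a number, and not every array correlated best with its own number. There the block gave 6 and 2, and it gave 11 in the mean and 1 for the interaction. The calls of Z00023161-1 at P14 (adjusted p = 0.204), Z00076265-1 in the mean (adjusted p = 0.0534) and Z00027353-1 in the interaction (adjusted p = 0.242) were lost, at unchanged differences between the genotypes. The call of Z00047679-1 at P31 was lost too.

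Leaving out each array in turn gave 6 to 13 probes at P10, 6 to 9 at P14, 3 to 269 at P31, 15 to 22 in the mean, 492 to 2733 for wild-type P14 against P10, 1232 to 2693 for wild-type P31 against P14, and 1 to 155 for the interaction. The highest values at P31 and for the interaction came without wild-type replicate 3 of P31, and those at P10 without knockout replicate 3 of P10. Without wild-type replicates 2 or 3 of P10 or replicate 3 of P14 the count of wild-type P14 against P10 was 492, 680 and 513. Among named probes, Z00047679-1 kept its call at P10, P14 and in the mean under every alternative and array left out. At P31 both it and Z00025973-1 (adjusted p = 0.160) lost the call with the 6 arrays alone. Z00047679-1 also lost its P31 call with an offset of 0, the log ratio of the scanner software and the deposited values. The same held without variance moderation, with the replicate number as a block and with array quality weights. Single probes kept their call, or shares their value, in 307 cases, with calls lost in 29 and shares moved in 21, apart from arrays left out. The call of Z00047679-1 at P31 is not in these counts. A kept call does not fix the size, and with Cy3 alone Z00047679-1 changed by -4.82, -5.55 and -5.09 at P10, P14 and in the mean. Between 53.3% and 63.7% of probes were well above background in Cy3, so changes of dimmer transcripts are bounds or not seen. Not run, for want of gene names, were the alternatives for gene lists.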

Other observations

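The test of displacement along the wild-type age course and the regroupings that part pairs were chosen only after the results were seen. Counts under other splits of the arrays were computed for each comparison. With 10 splits of 6 arrays into 3 and 3, no share under 0.05 can be reached. At P10 1 of 10 splits, the real one, gave as many probes, with 8 probes against a highest other of 0, both among the splits that part all 3 pairs of replicate numbers and among those that keep a pair together, and at P14 it was 1 of 10, with 7 against 1. At P31 it was 2 of 10, with 4 against 1075, which points to a structure among the arrays of that age. For wild-type P14 against P10 1 of 10 splits gave as many, with 1828 against 0, and for wild-type P31 against P14 it was 1 of 10, with 1897 against 1. For the mean over the ages 1 of 100 regroupings within ages gave as many, with 18 probes against a highest other of 2. Among 100 regroupings that part all 3 pairs of P10 it was 2 of 100, with 18 against 140, and among 100 that part the same numbers at every age, fitted with the replicate block, it was 3 of 100, with 11 against 37. The share was under the limit of 0.05 in each of these sets. In the latter sets it rests on few regroupings that reached the real count. Single ones called several times that count, which points to a structure among the arrays, so the latter sets do not exclude chance. For the interaction 11 of 100 regroupings gave as many in both of the latter sets, the real one included.

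A slower change with age in the knockout was considered as a hypothesis. Each knockout group was placed on the axis of the wild-type difference between the other ages, so that a value of -1 would set it back by the whole difference. The mean displacement was -0.0185 (0.0329 at P10, -0.0881 at P14 and -3.3e-04 at P31), with an SD of 0.0899 over 8000 regroupings and a two-sided exact permutation p of 0.806. On the slides with both genotypes it was 0.0718, -0.0297 and -0.361, with a mean of -0.106. The test leaves the hypothesis undecided. Over all arrays the displacement does not reach the -0.1 set for the hypothesis, while the mean on the slides, for which no p was computed, does. The spread between regroupings is too wide to exclude the hypothesis. The condition on that spread was added after the value was seen.

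A further hypothesis was that probes lower in the knockout are those that rise with age in the wild type. Of the 16 probes lower in the mean over the ages, 12 were higher at P31 than at P10 in the wild type, where 53.7% of all tested probes were higher (two-sided exact binomial p = 0.131). The share met the size set for the hypothesis and the test did not pass, so it stays undecided.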
